A study of Homo sapiens with 40 samples.

How the data were processed

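CUT&Tag maps a histone mark by tethering a transposase to the antibody bound to it, so that DNA beside the mark is tagged and sequenced. Per the labels, it was run on 120000 nuclei per reaction of human pluripotent stem cells for H3K27me3, placed by Polycomb repressive complex 2 on silenced genes, and H3K4me3, found at active and poised promoters. 40 libraries were used. 36 of them form 9 line-and-condition groups per mark with 2 replicates each: the induced lines Burb1, Fiaj1, Hehd1 and Sojd3, each untreated and after chromatin restoration (CHR), and the embryonic line H9 untreated. The other 4 are Sojd3 CHR cells at passages 37 and 38, 1 library per mark and passage. Per the labels, untreated cells grew in E8 medium on vitronectin, and CHR cells in StemFlex medium on laminin with 3 µM IWP2, which blocks WNT secretion. These conditions come from the growth protocol, while the treatment field gives no treatment for CHR and untreated samples alike. Medium, matrix and inhibitor therefore differ together between the conditions. The labels do not say for each induced line whether it forms cerebral organoids. The protocol lists an IgG control antibody, which was not analysed here.

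The deposited tables, made by the authors, list regions of the GRCh38 genome and 1 value per library for each region. The submitters' processing notes name SEACR 1.3 and SAMtools 1.21 without a role or an order. The aligner, the handling of duplicate reads and the antibodies are not given in the sources used here. The values deposited by the authors were taken as log2 RPM, reads per mega (M) reads of the library's own total. Of the values under 200 reads, all lay within 0.02 of a whole read once converted back, and regions without reads hold the value of 0.9 read, which was set to 0. This fixes the size of 1 read but not the divisor, so all depths in M reads rest on that reading. Reads in regions then made up 75.02% to 89.24% of the totals for H3K27me3 and 75.72% to 93.47% for H3K4me3. Dividing by the library total makes every value a share, so a change in a few very strong regions moves all others, and a change of a mark over the whole genome cannot be seen. The later passages come in tables of their own with the same regions, each scaled to its own total. PCR duplicates cannot be told from independent fragments here, so read numbers cover counting error only.

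The tables hold 48016 H3K27me3 regions (41949 on autosomes, median width 5151 bp) and 25120 H3K4me3 regions (24150 on autosomes, median width 3499 bp). Autosomal regions with a mean of at least 2 RPM over the 18 libraries of a mark were tested, which left 26031 for H3K27me3 and 19565 for H3K4me3. This filter was chosen after the tables were seen and before any test result. Values were taken as log2(RPM + 1), so fold changes of weakly covered regions are understated. limma 3.58.1 with a mean-variance trend (R 4.3.3) was fitted to the 9 groups of each mark, with 9 residual degrees of freedom. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the regions of a mark, and a region is called at an adjusted p under 0.05. Errors beside log2 changes are standard errors from this model, which measure the spread between replicates within groups and not that between lines. The alternative with replicates summed takes the line as the replicate, with its spread moderated over regions. The count-based tests planned before the data were examined were replaced by this fit, since the unit found in the tables is not a read count. Reads could be recovered from the values, so this was a choice, and limma voom on those reads was run as an alternative.

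The comparisons were CHR against untreated as the mean of the 4 lines and within each line, the difference of the CHR effect between lines, untreated lines against H9 and CHR lines against H9. H9 has no CHR libraries, so line and condition are compared with it only as means. Distances from H9 were compared over the 4 lines by an exact paired permutation test, two-sided, whose smallest possible p is 0.125. The change after CHR and the distance from H9 share the untreated libraries, so their correlation was taken with 1 untreated replicate on each side. It was also taken without this split and set against simulated noise on the log2 scale, without an effect or differences between lines. Correlations over regions describe regions, which are not independent replicates.

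Genes came from the RefSeq annotation of 20037 protein-coding genes, which gives no strand here. A region was therefore assigned to a gene when it overlapped 2500 bp around either annotated end, and no promoter is meant. 7362 genes had a tested H3K27me3 region and 14228 a tested H3K4me3 region. Genes that share a region are counted in their lists but have 1 measurement. 18 gene lists with 349 members were fixed before the data were examined. They cover anterior epiblast and forebrain, midbrain with hindbrain and spinal cord, posterior epiblast and primitive streak, WNT targets and feedback, WNT ligands and Frizzled receptors, HOX genes, core and naive pluripotency, definitive endoderm, mesoderm, amnion and trophoblast, neural crest and surface ectoderm, fibroblast, loci variable between reprogrammed lines, clustered protocadherins, imprinted genes, Polycomb and Trithorax, and housekeeping genes. Lists were tested with camera at its preset correlation and again with an estimated correlation. camera sets the regions of a list against all other tested regions of the mark. List regions all lie at gene ends, so a list can also stand out as gene ends do.

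The rule for named genes was fixed before the data were examined. It took the 10 largest rises and the 10 largest falls (5 of each against H9, 3 of each within a line) among called regions at or above the median level, at an end of a protein-coding gene. The sign had to be the same in all 4 lines for CHR against untreated, and for all 4 lines against H9, with no such condition within a line. It added called members of the lists, up to 4 per list and direction (3 against H9), and 9 genes in any case: PAX6, EOMES, SOX1, SIX3, TBXT, OTX2, MIXL1, SOX2 and POU5F1. List members and these 9 genes are represented by their region of highest mean, other genes by their region of lowest p. Any other gene named was chosen after its values were seen. 1 gene that the rule took within a line is not reported here.

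Over the 18 libraries per mark in the fit, without the later passages, depth was 1.54 to 31.54 M reads for H3K27me3 and 1.7 to 15.06 M reads for H3K4me3. Reads were simulated at these depths, with 100 regions changed per fold. All regions and libraries of a mark shared 1 common spread beyond counting error, taken from the more strongly covered real regions. Real H3K27me3 replicates spread unequally, with a root mean square log2 difference of 0.404 in untreated Sojd3 and 0.951 in Sojd3 CHR. The rates below hold for the simulated spread and the simulated share of changed regions only. In these reads the 4-line comparison recovered 54% of 2-fold and 98% of 4-fold changes for H3K27me3, with 8 false calls. For H3K4me3 it recovered 95% and 100%, with 11 false calls. Single lines recovered 3% to 4% of 2-fold and 34% to 47% of 4-fold changes for H3K27me3, and 35% to 49% and 88% to 90% for H3K4me3. The test of differences between lines made 0 false calls in either mark. In these simulated reads single lines therefore missed many H3K27me3 changes of 4-fold and below, and many H3K4me3 changes of 2-fold. Few regions were changed there, whereas limma called 29.03% of real H3K27me3 regions over the 4 lines and 20.78% to 28.94% in Burb1, Fiaj1 and Sojd3. The adjustment is less strict where more regions change. The rates therefore cannot be carried over to the H3K27me3 counts of these lines or of the 4-line comparison.

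Alternatives were median-of-ratios size factors, totals over the listed regions, limma voom on the recovered reads, pseudocounts of 0.1 and 5, no filter, X and Y included, a 2-fold minimum, a replicate block, replicates summed, gene windows of 1000 and 5000 bp, each library left out, each line left out, reads thinned to the shallowest library, and only libraries of at least 3 M reads. Preparation used Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9.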

Results

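H3K27me3 and H3K4me3 were mapped in 4 human induced pluripotent stem cell lines, Burb1, Fiaj1, Hehd1 and Sojd3, before and after chromatin restoration (CHR), a culture regime meant to bring chromatin to the state of lines that form cerebral organoids without guidance. H9, an embryonic stem cell line used as the naturally competent reference, was measured untreated. Each line and condition had 2 replicates per mark. For H3K27me3, replicates 1 and 2 held 6.8 and 9.06 mega (M) reads in untreated Burb1, 1.54 and 14.4 in untreated Fiaj1, 10.47 and 11.95 in untreated Hehd1, 9.25 and 11.65 in untreated Sojd3, and 31.54 and 11.44 in H9. The CHR libraries held 1.89 and 12.77 in Burb1, 10.7 and 7.97 in Fiaj1, 1.61 and 2.26 in Hehd1, and 17.52 and 1.56 in Sojd3. For H3K4me3 they held 7.48 and 8.5 in untreated Burb1, 1.9 and 10.25 in untreated Fiaj1, 9.84 and 10.61 in untreated Hehd1, 6.16 and 8.84 in untreated Sojd3, and 9.58 and 15.06 in H9. The H3K4me3 libraries of CHR cells held 1.7 and 8.25 in Burb1, 9.88 and 12.51 in Fiaj1, 1.72 and 2.36 in Hehd1, and 10.84 and 2.18 in Sojd3. Sojd3 CHR cells at passages 37 and 38 gave 13.72 and 10.16 M reads for H3K27me3 and 16.48 and 11.87 for H3K4me3. The same 5 samples lay under 3 M reads in both marks: 4 of the 8 CHR samples, both of Hehd1 among them, and 1 of the 10 untreated samples. Replicates correlated across regions at Pearson 0.887 to 0.972 for H3K27me3 and 0.934 to 0.986 for H3K4me3.

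In a principal component analysis of H3K27me3, untreated Burb1, Fiaj1 and Sojd3 stood apart from all other samples on the first component. The first component held 42.58% of the variance, and these 6 libraries lay at 86.93 to 157.42 on it. All CHR libraries, H9 and untreated Hehd1 lay at −73.87 to −15.51. On the second component, with 15.53%, the 4 CHR libraries under 3 M reads lay at 38.95 to 60.24, both of Hehd1 among them, and the other CHR libraries at −35.99 to −14.89, with untreated Hehd1 at −31.26 and −27.72. This component did not follow depth alone. The deeper untreated libraries of Burb1 lay at 83.11 and 61.36 and those of Sojd3 at −87.54 and −84.62. The untreated Fiaj1 library under 3 M reads lay at −1.99. The first component of H3K4me3 held 20.95% and separated untreated Burb1, Fiaj1 and Sojd3, at 6.48 to 68.25, from all others, at −29.5 to −7.99.

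**Figure D1:**
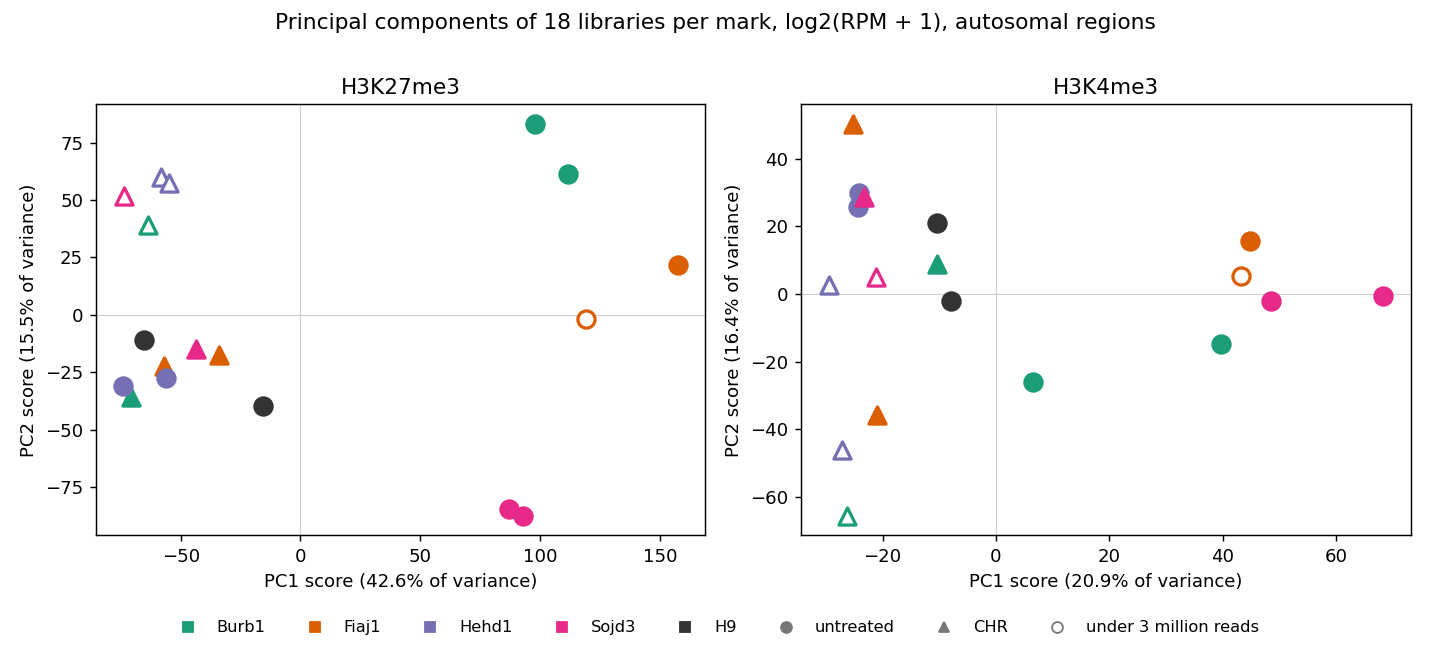
Principal components 1 and 2 of log2(RPM + 1) in tested regions for each mark, with the percent of variance on each axis; colours are lines, circles untreated, triangles CHR, and open symbols libraries under 3 M reads. Untreated Burb1, Fiaj1 and Sojd3 lie on the right, at 86.93 to 157.42 for H3K27me3, and in the H3K27me3 panel alone the CHR libraries under 3 M reads lie above untreated Hehd1 and the deeper CHR libraries, at 38.95 to 60.24 on the vertical axis. The deeper untreated Burb1 libraries lie higher still, at 61.36 and 83.11.

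The main comparison asked which regions CHR changed on average over the 4 lines. H3K27me3 rose at ends of genes such as ONECUT1 and TBX1 and fell at others, such as KCTD16 and FABP7, that held little of it in H9. At the ends of ONECUT1, a liver and pancreas transcription factor (chromosome 15, 52778249 to 52808600), it rose by 3.29 ± 0.2 on the log2 scale (SE between replicates, mean of 4 lines, adjusted p = 1.75e-10), from 193 to 670 RPM with 687 in H9. It rose by 3.26 ± 0.26 at TBX1, a regulator of the pharyngeal arches, by 3.54 ± 0.24 at BAHCC1, which encodes a reader of H3K27me3, and by 3.71 ± 0.33 at the phosphatase gene DUSP8. At KCTD16, an auxiliary subunit of GABA-B receptors (chromosome 5, 144487849 to 144520200), it fell by 4.21 ± 0.23 (adjusted p = 4.15e-11), from 146 to 2.87 RPM with 3.7 in H9. NPSR1, the neuropeptide S receptor, fell by 4.08 ± 0.32, FABP7, a fatty acid binding protein of radial glia, by 3.9 ± 0.2, and LMAN1, a cargo receptor of the secretory pathway, by 3.84 ± 0.2. The spread over untreated lines was wide, with SDs of 113 RPM at KCTD16 and 419 RPM at TBX1, against 0.734 and 193 RPM over CHR lines (n = 4). The H9 replicates also differed, with a mean of 921 RPM and an SD of 688 at TBX1, and 63.1 and 65.2 at DUSP8. The errors given measure the spread between replicates and not that between lines, in which ONECUT1 ran from 0.19 in Hehd1 to 5.68 in Sojd3. With replicates summed and the line as the replicate, the 8 genes named in this paragraph kept their calls.

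The other large rises lay at KRTAP10-12, EXOC3L4, SLC17A9, the sodium-iodide symporter gene SLC5A5, the cation channel gene TRPM2 and the region shared by ATP13A3 and GP5, between 3.24 ± 0.18 and 3.69 ± 0.28. Not all of them ended near H9. In RPM, SLC5A5 went from 5.27 to 52 with 3.47 in H9, and EXOC3L4 from 66 to 241 with 9.94. ATP13A3 went from 26.1 to 122 with 36.4, TRPM2 from 3.43 to 44 with 16.1 and SLC17A9 from 13.4 to 52.5 with 27.5. KRTAP10-12 went from 64.9 to 319 with 284 in H9 (SD 223). The other large falls lay at PHF3, FEZ2, the aldehyde dehydrogenase gene ALDH1B1, the guanylate cyclase gene GUCY2C, the complement gene C8B and the spindle checkpoint gene BUB1, between −3.78 ± 0.28 and −3.19 ± 0.17. Among the genes fixed in advance, SIX3, a forebrain regulator (chromosome 2, 44920249 to 44961150), rose by 2.34 ± 0.17 (adjusted p = 2.01e-09), from 486 to 1410 RPM with 1350 in H9. OTX2, a regulator of the anterior epiblast and forebrain (chromosome 14, 56789899 to 56875350), fell by 1.54 ± 0.13 (adjusted p = 8.75e-09), from 996 to 290 RPM with 423 in H9. MIXL1, a primitive streak regulator, rose by 1.17 ± 0.2, a call that ended without the line Fiaj1 (0.63). The neural gene SOX1 rose by 0.51 ± 0.13 (adjusted p = 0.004), a call that ended with median-of-ratios size factors (0.43), without the line Sojd3 (0.39) and with only libraries of at least 3 M reads (0.42). PAX6 (0.3 ± 0.14, adjusted p = 0.119), EOMES (0.23 ± 0.12, 0.151) and TBXT (0.24 ± 0.12, 0.168) did not pass the test, and POU5F1 and SOX2 had no tested region. With the line as the replicate, SIX3 and OTX2 kept their calls and MIXL1 and SOX1 lost theirs.

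limma called 7556 of 26031 regions (29.03%), 3667 higher and 3889 lower after CHR, and 4047 of them differed at least 2-fold. Of the regions that rose, 52.6% lay at a gene end and 69.59% overlapped an H3K4me3 region. Of those that fell, 25.35% lay at a gene end and 29.8% overlapped an H3K4me3 region, against 20.03% and 19.62% of regions not called. Median widths were 8051, 9701 and 6551 bp for regions that rose, fell and were not called, and median levels 9.65, 7.71 and 3.9 RPM. The shares were not matched for width or level. With replicates summed, which leaves 1 value per line and condition, 1752 regions were called. With only libraries of at least 3 M reads, which leaves Hehd1 out of the mean, 12678 were called. Over both marks, 86 values of named genes lost their call with the line as the replicate and 88 stayed on their side of the test.

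**Figure D2:**
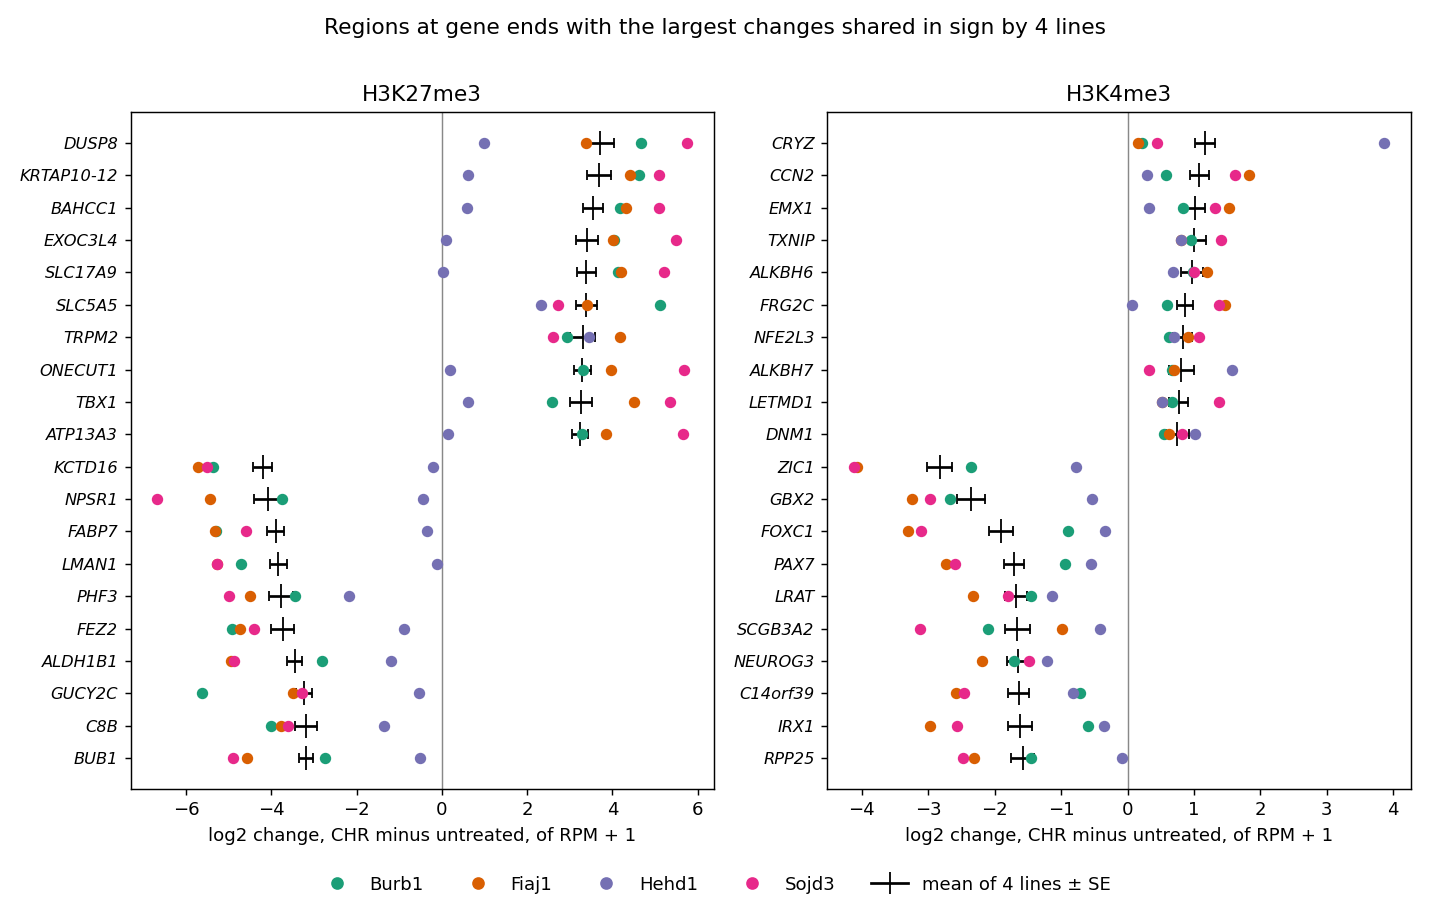
The 10 largest rises and 10 largest falls per mark, as the log2 change after CHR. Coloured points are the 4 lines and black marks their mean, with an SE from the spread between replicates. Hehd1 lies closest to 0 at most H3K27me3 genes, as at KCTD16 (−0.2 against a mean of −4.21).

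In the list of anterior epiblast and forebrain genes, 9 of 21 measured members rose and 4 fell (9 and 4 adjusted over the list alone). ZIC2 rose by 2.23 ± 0.19, ZIC1 and ZIC4 by 1.99 ± 0.13 in their shared region and FEZF1 by 1.6 ± 0.17, while the POU factor gene POU3F1 and the secreted WNT antagonist gene SFRP1 each fell by 1.14. In the midbrain, hindbrain and spinal cord list, 8 of 17 rose and 0 fell (10 and 0 adjusted over the list alone), led by GBX2 at 2.84 ± 0.16, which sets the border of midbrain and hindbrain, and PAX5 at 2.58 ± 0.18. In the posterior epiblast and primitive streak list, 12 of 26 rose and 3 fell (14 and 4 adjusted over the list alone). NKX1-2 rose by 2.94 ± 0.22, SP8 by 2.87 ± 0.2 and CDX1 by 2.71 ± 0.17, whereas CER1 fell by 3.16 ± 0.31 and LEFTY2 by 3 ± 0.29. CER1 and LEFTY2 both encode secreted antagonists of NODAL signalling. camera adjusted p was 0.0306 for forebrain, 0.00209 for midbrain with hindbrain and 0.00124 for streak. With an estimated correlation, adjusted p = 0.476, 0.41 and 0.311. Every list had a rise as its camera direction for H3K27me3. Of risen regions 52.6% lay at a gene end, against 20.03% of those not called. Here and in the lists below, camera therefore does not tell list genes from gene ends in general.

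Among WNT targets and feedback genes, 5 of 12 rose and 1 fell (6 and 1 adjusted over the list alone), with NKD2 at 2.04 ± 0.27 and NOTUM at 1.42 ± 0.26, both inhibitors of WNT signalling. camera adjusted p was 0.0306, and adjusted p = 0.311 with an estimated correlation. Of 25 WNT ligands and Frizzled receptors, 9 rose and 4 fell (10 and 5 adjusted over the list alone, camera 0.502). WNT7B rose by 1.63 ± 0.24, while the receptor gene FZD7 fell by 2.05 ± 0.22 and WNT8B by 1.57 ± 0.16. In the amnion and trophoblast list 4 of 9 rose (4 adjusted over the list alone), led by KRT7 at 2.51 ± 0.18 and TFAP2C at 2.03 ± 0.21, and in neural crest and surface ectoderm 5 of 10 (5 adjusted over the list alone), led by FOXD3 and SOX10, the latter at 1.42. camera adjusted p was 0.0165 and 0.0314, and adjusted p = 0.315 and 0.269 with an estimated correlation. Of 42 clustered protocadherins, which share 19 regions, 18 rose (19 adjusted over the list alone), with PCDHGC4 and PCDHGC5 at 2.52 ± 0.24. These 18 lie in 9 regions, and 8 of them, PCDHB10 and PCDHB11 included, share 1 region. It rose by 1.88 ± 0.19, a call that ended without the line Burb1 (0.42), with 6.23, −0.25, 1.43 and 0.09 in Burb1, Fiaj1, Hehd1 and Sojd3. camera adjusted p for the protocadherins was 0.00209, and adjusted p = 0.227 with an estimated correlation. Of 17 imprinted genes, 8 rose and 3 fell (11 and 3 adjusted over the list alone). GNAS rose by 2.83 ± 0.28, CDKN1C by 2.36 ± 0.22 and DLK1 by 2.04 ± 0.24, and ZDBF2 fell by 2.91 ± 0.18. Their camera adjusted p was 0.0196, and adjusted p = 0.311 with an estimated correlation.

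The remaining lists passed no camera test. In mesoderm 7 of 16 rose and 1 fell (7 and 1 adjusted over the list alone, camera 0.0639), with FOXC1 at 2.08 ± 0.14 and TCF15 at −1.1, the latter a call that ended without the line Sojd3 (−0.59). UTF1 rose by 2.9 ± 0.27 as 1 of 3 core pluripotency genes (2 adjusted over the list alone, camera 0.142), in a region that VENTX and KNDC1 share. KLF4 and TFCP2L1 (0.76) rose among 8 naive pluripotency genes (2 adjusted over the list alone, camera 0.498), calls that ended without the line Burb1 (0.85 and 0.45). Among 10 endoderm genes HHEX rose by 1.43 ± 0.15, FOXA2 rose by 0.48 and CER1 fell (2 and 1 adjusted over the list alone, camera 0.934), a list whose median of −0.02 has the opposite sign of its camera test. The call at FOXA2 ended with median-of-ratios size factors (0.41) and without the line Sojd3 (0.26). TWIST2 rose by 1.93 ± 0.18 among 4 fibroblast genes (2 adjusted over the list alone, camera 0.346). Of 9 loci variable between reprogrammed lines 4 rose and 1 fell (4 and 1 adjusted over the list alone, camera 0.516), with DPP6 at 0.91, a call that ended without the line Burb1 (0.34). Of 8 Polycomb and Trithorax genes, the H3K27 demethylase gene KDM6B rose by 1.4 ± 0.26, CBX2 and CBX8 by 0.66 ± 0.17, and CBX7 fell by 0.89 ± 0.19 (3 and 2 adjusted over the list alone, camera 0.934). The call at CBX2 and CBX8 ended with median-of-ratios size factors (0.59) and with only libraries of at least 3 M reads (0.61). HOXB13 rose by 0.58 ± 0.12 as the 1 called of 39 HOX genes, which lie in 5 regions (1 adjusted over the list alone, camera 0.476), and was not called without the line Sojd3 (0.34) or with only libraries of at least 3 M reads (0.39). The 1 housekeeping gene measured was not called by limma (0 adjusted over the list alone, 0 at an unadjusted p under 0.05, change 0.3, camera 0.584).

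**Figure D3:**
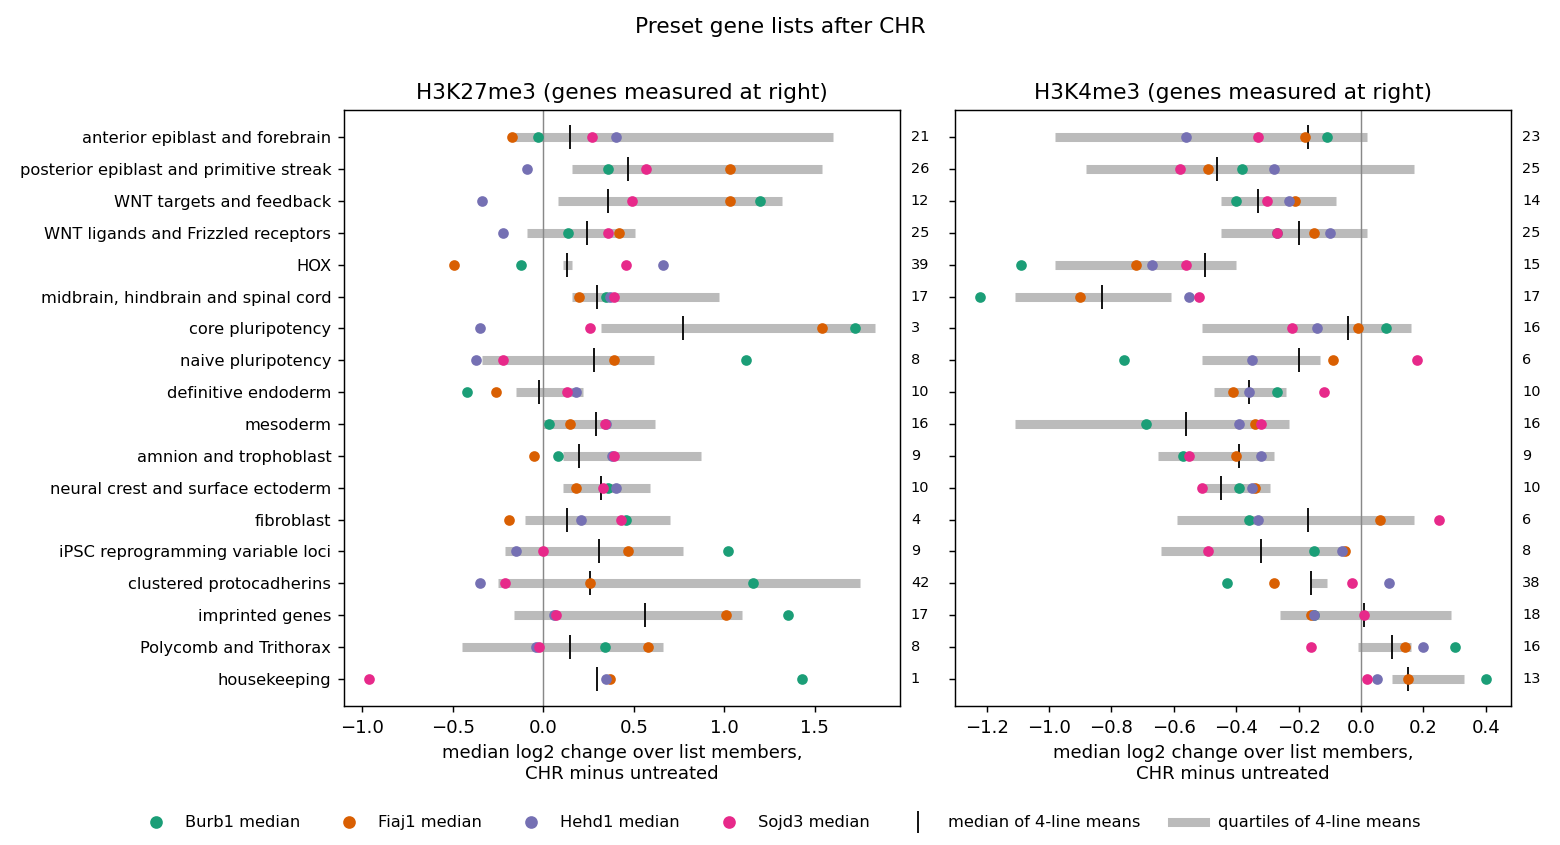
Change after CHR in the 18 gene lists for each mark, in log2 units; coloured points are line medians, black ticks the median of the 4-line means and grey bars its quartiles, with the number of genes measured. For H3K4me3 the midbrain, hindbrain and spinal cord list has the lowest median, −0.83.

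The response was also measured within each line. In Burb1, Fiaj1 and Sojd3 the largest falls of H3K27me3 included KIAA1586, at −6.22 ± 0.36, −7.59 ± 0.36 and −6.52, and KCTD16, at −5.38, −5.72 and −5.52 (n = 2 replicates). In Hehd1 the KIAA1586 region differed by 0.69 and KCTD16 by −0.2. The largest rises were CCR10 (6.63 ± 0.51) and PCDHB10 (6.23 ± 0.38) in Burb1, LMO3 (4.81 ± 0.61) in Fiaj1 and DUSP8 (5.76) and ONECUT1 (5.68) in Sojd3. In Hehd1 MOS, a kinase gene of oocytes, rose by 4.51 ± 0.35. limma called 7533 regions in Burb1 (4843 higher), 6087 in Fiaj1 (4200 higher), 5409 in Sojd3 (1572 higher) and 365 in Hehd1 (60 higher). Across regions the changes correlated at Pearson 0.71 between Burb1 and Fiaj1, 0.54 between Burb1 and Sojd3 and 0.75 between Fiaj1 and Sojd3, and at −0.03, −0.07 and 0.1 between these lines and Hehd1.

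The share of single-line calls that were higher moved with the scaling. The median change over all regions was 0.51 in Burb1, 0.42 in Fiaj1, −0.47 in Hehd1 and −0.34 in Sojd3, and −0.01, −0.01, −0.03 and −0.04 with median-of-ratios size factors. Called regions were higher in 64.29%, 69%, 16.44% and 29.06% of cases, and in 32.72%, 44.32%, 67.86% and 43.89% with those factors, which kept 62.75%, 69.48%, 26.3% and 79.24% of the calls. Leaving out 1 library moved some counts by over 1.5 times. Burb1 fell to 4513 without its CHR replicate 2 and to 4547 and 4757 without untreated replicates 1 and 2, Fiaj1 to 3105 without its CHR replicate 2, and Sojd3 to 3162 without its CHR replicate 2 and 2910 and 3196 without untreated replicates 1 and 2. The 365 calls in Hehd1 became 17 and 8 without its untreated replicates 1 and 2, 172 and 712 without its CHR replicates 1 and 2, and 934 and 937 without Sojd3 CHR replicates 1 and 2. They became 203 without either untreated Burb1 replicate, 162 and 163 without Fiaj1 CHR replicates 1 and 2, and 153 and 150 without untreated Sojd3 replicates 1 and 2.

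The CHR effect on H3K27me3 was tested for a difference between lines, and 9275 regions (35.63%) differed. They included 4414 (58.42%) of the 7556 regions called over the 4 lines. At KCTD16, ONECUT1, SIX3 and OTX2 the effect differed between lines, with Hehd1 at −0.2, 0.19, 0.61 and −0.13. At TRPM2 it did not pass this test (adjusted p = 0.394), with 2.94, 4.18, 3.46 and 2.61 in Burb1, Fiaj1, Hehd1 and Sojd3. The called regions moved the same way in all 4 lines in 3408 cases (45.1%), 893 higher and 2515 lower, and the same way in Burb1, Fiaj1 and Sojd3 in 6503 cases (86.06%). The count of 9275 fell to 5234 and 6148 without untreated Hehd1 replicates 1 and 2, to 5471 with median-of-ratios size factors, to 5213 with reads thinned to the shallowest library and to 4969 with only libraries of at least 3 M reads.

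H3K4me3 fell at many of the genes where H3K27me3 rose. At ZIC1 and ZIC4, which share a region (chromosome 3, 147403301 to 147415950), it fell by 2.83 ± 0.19 on the log2 scale (SE between replicates, mean of 4 lines, adjusted p = 3.2e-10), from 231 to 21 RPM with 24.4 in H9. At GBX2 (chromosome 2, 236158351 to 236175700) it fell by 2.36 ± 0.21 (adjusted p = 2.79e-08), from 164 to 25.1 RPM with 38.7 in H9. PAX7, a gene of dorsal neural and muscle progenitors, fell by 1.71 ± 0.15, FOXC1, a mesoderm regulator, by 1.91 ± 0.18, and NEUROG3, an endocrine pancreas regulator, by 1.65 ± 0.17. LRAT, SCGB3A2, IRX1, RPP25 and the region of C14orf39 and SIX6 fell by 1.58 to 1.68. Among the 10 largest rises that the rule took, CCN2, a matrix protein gene, rose by 1.08 ± 0.14, from 33.4 to 66.7 RPM, the forebrain gene EMX1 by 1.01 ± 0.16 and TXNIP, an inhibitor of thioredoxin, by 1 ± 0.18. ALKBH6 with SYNE4, FRG2C, NFE2L3, ALKBH7, LETMD1 and DNM1 rose by 0.75 to 0.97, and the calls at ALKBH7 (0.5) and DNM1 (0.49) ended with only libraries of at least 3 M reads. CRYZ and TYW3 rose by 1.17 ± 0.15, a call that rested on Hehd1 (3.86) and ended without that line (0.27) and with only libraries of at least 3 M reads (0.31). With the line as the replicate, ZIC1, GBX2, PAX7, NEUROG3, LRAT, RPP25, C14orf39, TXNIP, ALKBH6 and NFE2L3 kept their calls, and FOXC1, SCGB3A2, IRX1, CCN2, EMX1, CRYZ, FRG2C, ALKBH7, LETMD1 and DNM1 lost theirs.

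Of the genes fixed in advance, SIX3 fell by 1.52 ± 0.21 in H3K4me3 (adjusted p = 2.13e-05), SOX1 by 1.23 ± 0.22 (0.000373) and EOMES by 1.08 ± 0.17 (0.000118). PAX6 fell by 0.66 ± 0.19 (adjusted p = 0.0216), a call that ended without Burb1 CHR replicate 2 (−0.48), untreated Burb1 replicate 1 (−0.57), untreated Fiaj1 replicate 2 (−0.61), Hehd1 CHR replicate 1 (−0.59), untreated Hehd1 replicate 2 (−0.62), Sojd3 CHR replicate 2 (−0.63) or untreated Sojd3 replicate 2 (−0.61). TBXT fell by 0.55 ± 0.16 (adjusted p = 0.0214), a call that ended without Burb1 CHR replicate 2 (−0.44), untreated Hehd1 replicate 1 (−0.51), Sojd3 CHR replicate 1 (−0.5) or untreated Sojd3 replicate 2 (−0.51). SOX2 (0.23 ± 0.23, adjusted p = 0.583), OTX2 (0.33 ± 0.2, 0.332), MIXL1 (−0.06 ± 0.22, 0.9) and POU5F1, whose region TCF19 shares (−0.02 ± 0.22, 0.971), did not pass the test. With the line as the replicate, EOMES and PAX6 kept their calls and SIX3, SOX1 and TBXT lost theirs. limma called 2311 of 19565 regions (11.81%), 706 higher and 1605 lower, and 654 of them differed at least 2-fold. Of the regions that fell, 65.86% overlapped an H3K27me3 region, against 37.25% of those that rose and 44.2% of those not called. The regions that fell were also wider (median 5349 bp against 3299 and 3999 bp) and stronger (34.4 RPM against 9.29 and 22.8). Wider regions overlap others more often, and the shares were not matched for width or level. The called regions were higher in 30.55% of cases and in 42.45% with median-of-ratios size factors. Without the line Sojd3 1467 regions were called, with replicates summed 269, and 55.47% of the calls were made again with only libraries of at least 3 M reads.

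In the midbrain, hindbrain and spinal cord list, 12 of 17 genes fell in H3K4me3 (13 adjusted over the list alone), among them EN2 by 1.82 ± 0.26 and LMX1B by 1.55 ± 0.24. Of 15 HOX genes 6 fell (7 adjusted over the list alone), with HOXB13 at −3.18 ± 0.22 in a region shared with PRAC1 and PRAC2, HOXC4 at −2.43 ± 0.24 and HOXB2 at −1.48 ± 0.22. Of 16 mesoderm genes 7 fell (11 adjusted over the list alone), such as KDR at −1.38 ± 0.14 and PDGFRA at −1.09 ± 0.15, both receptor genes. camera adjusted p was 1.75e-09, 7.9e-07 and 1.92e-05 for these lists, and adjusted p = 0.452 for each with an estimated correlation. In the streak list 11 of 25 fell and 1 rose (13 and 2 adjusted over the list alone), with GSC at −1.24 ± 0.19 and NKX1-2 at −1 ± 0.14. CER1 rose by 1.36 ± 0.32 at a low level, 0.823 to 5.01 RPM, a call that ended without the line Fiaj1 (0.86). Of 23 forebrain genes 9 fell (9 lower and 1 higher adjusted over the list alone), ZIC1 and SIX3 among them, and of 14 WNT targets 4 fell (4 adjusted over the list alone), with LEF1, a transcription factor of the pathway, at −0.61 ± 0.13. camera adjusted p was 0.00669, 0.0042 and 0.0219, and adjusted p = 0.547 for each with an estimated correlation.

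Of 10 endoderm genes 4 fell and CER1 rose (5 and 1 adjusted over the list alone), with HHEX at −1.22 ± 0.17. Of 9 amnion and trophoblast genes 3 fell (5 adjusted over the list alone), with TFAP2C at −1.07 ± 0.15, and of 10 neural crest genes 2 fell (3 adjusted over the list alone), with MSX2 at −0.87 ± 0.2. PPIA rose by 0.44 among 13 housekeeping genes (2 adjusted over the list alone), which had a median of 0.15. camera adjusted p was 0.0498, 0.0106, 0.0235 and 0.0495, and adjusted p = 0.547 for each with an estimated correlation. Among 16 core pluripotency genes UTF1 fell by 2.28 ± 0.25 and NANOG by 1.15 ± 0.2, with GDF3 the other of 3 falls. NANOG went from 257 to 111 RPM with 188 in H9 (5 adjusted over the list alone, camera 0.222). TBX3 fell by 1.08 and KLF4 by 0.61 among 6 naive genes (2 lower and 1 higher adjusted over the list alone, camera 0.256), calls that ended without Fiaj1 (−0.84) and without Sojd3 (−0.58). Of 25 WNT ligands and Frizzled receptors 3 fell, with FZD10 at −0.84 ± 0.18, and FZD7 rose by 0.73 ± 0.17 (4 and 1 adjusted over the list alone, camera 0.196). The call at FZD7 ended without the line Fiaj1 (0.54) and that at FZD10 without Sojd3 (−0.72).

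PCDHA6 rose by 3.54 ± 0.23 in H3K4me3, from 0.403 to 21.2 RPM with 38.7 in H9, as the 1 rise among 38 clustered protocadherins, of which 4 fell (1 and 4 adjusted over the list alone). The median of this list, −0.16, has the opposite sign of its camera test (0.974). Among 18 imprinted genes MEG3 rose by 1.27 ± 0.19 and 3 fell (2 and 4 adjusted over the list alone, camera 0.667). The MEG3 change came from Burb1 (5.23) and was −0.05 without that line. Of 6 fibroblast genes 2 fell (3 adjusted over the list alone, camera 0.518), with TBX15 at −0.62, a call that ended without Sojd3 (−0.58). Of 8 loci variable between reprogrammed lines 2 fell, FZD10 among them (3 adjusted over the list alone, camera 0.0777). Of 16 Polycomb and Trithorax genes limma called 0 (0 adjusted over the list alone, 3 at an unadjusted p under 0.05, median 0.1, camera 0.235).

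Within lines, ZIC1 fell by 4.07 in Fiaj1 and by 4.12 ± 0.37 in Sojd3 in H3K4me3, GBX2 by 2.67 in Burb1 and 3.25 in Fiaj1, and SCGB3A2 by 3.13 in Sojd3. SYNPO2, an actin-binding protein gene, rose by 2.08 in Fiaj1 and 2.19 in Sojd3, and ZNF732 by 1.94 ± 0.34 in Burb1. In Hehd1 the largest rises were at NAA60 and ZNF597 (4.71 ± 0.32), the proteasome assembly gene PSMD5 (3.93 ± 0.3) and CRYZ. limma called 628 regions in Burb1 (118 higher), 512 in Fiaj1 (191 higher), 725 in Sojd3 (354 higher) and 252 in Hehd1 (93 higher), and 560 regions (2.86%) differed between lines. The share of higher regions in Hehd1 was 36.9%, and 58.43% with median-of-ratios size factors. Of the 2311 regions called over the 4 lines, 1689 (73.09%) moved the same way in each line, 393 higher and 1296 lower.

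These H3K4me3 counts moved with single libraries. Burb1 fell to 339 without its CHR replicate 2 and 389 without its untreated replicate 2, Fiaj1 to 233 and 257 without its untreated replicates 1 and 2, and Sojd3 to 346 and 386 without its CHR replicates 1 and 2 and 282 and 476 without its untreated replicates 1 and 2. The 252 calls in Hehd1 became 83 without its CHR replicate 1, 37 and 33 without its untreated replicates 1 and 2, 380 without Burb1 CHR replicate 1, and 639 and 609 without Fiaj1 CHR replicates 1 and 2. The 560 regions that differed between lines became 1003 without Fiaj1 CHR replicate 1, 288 and 305 without untreated Hehd1 replicates 1 and 2, 370 without Sojd3 CHR replicate 1 and 344 without untreated Sojd3 replicate 1.

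Both marks were measured at the ends of 4141 genes, and their changes were opposed. Of 444 genes called in both, 383 gained H3K27me3 and lost H3K4me3, among them ZIC1, GBX2, SIX3 and FOXC1. FZD7 and CER1 were among 27 genes with the reverse, 23 genes rose in both marks and 11 fell in both. The changes correlated across genes at Pearson −0.33 and Spearman −0.34, and at −0.21 in Burb1, −0.29 in Fiaj1, 0.04 in Hehd1 and −0.37 in Sojd3. Fisher's exact test gave an odds ratio of 0.025 (p = 5.73e-21, two-sided), with genes taken as independent although neighbours share regions.

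**Figure D4:**
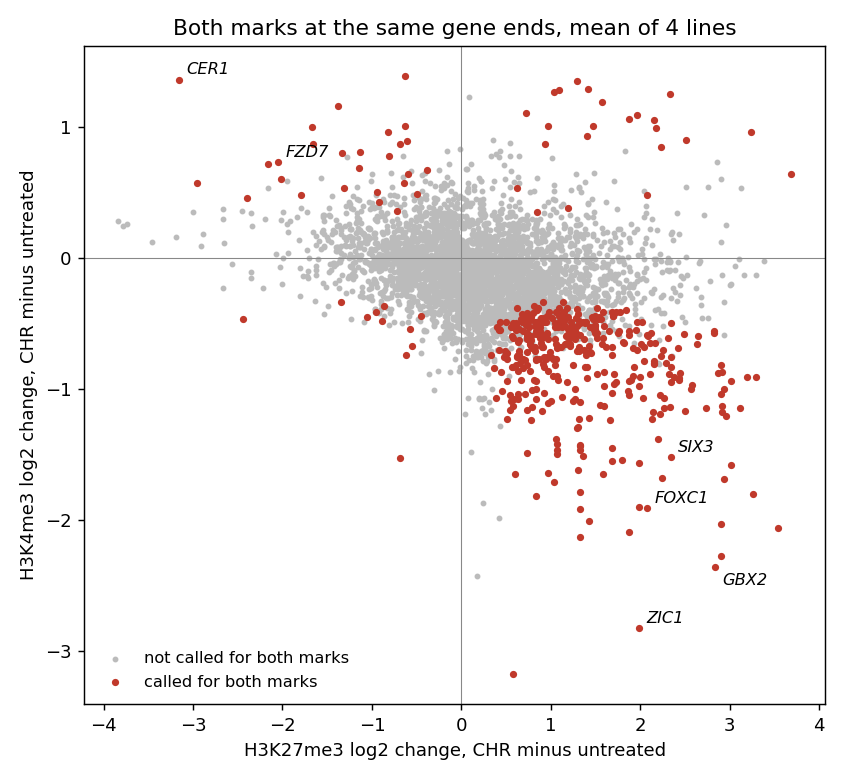
Log2 change after CHR of H3K27me3 (horizontal) and H3K4me3 (vertical) at the ends of 4141 genes, as means of 4 lines; red points are the 444 genes called for both marks and grey points the others. Of the red points 383 lie at lower right, where H3K27me3 rose and H3K4me3 fell.

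The untreated lines were compared with H9 to find where they differed before CHR. H3K27me3 was higher in them at TGFA, a growth factor gene, by 6.54 ± 0.33 on the log2 scale (SE between replicates, mean of 4 lines against 2 H9 libraries), at 288 against 1.47 RPM, and at CCDC177 by 5.55 ± 0.33, FABP12 by 5.27 ± 0.31 and TACR1, a neurokinin receptor gene, by 4.39 ± 0.29. It was lower at the signalling gene PIK3R1 (−3.78 ± 0.31), at SP8 (−3.66 ± 0.31), a patterning gene of brain and limb, at RNF220 (−3.42 ± 0.35) and at ONECUT1 (−3.32 ± 0.32). SIX3 was lower (−2.25 ± 0.28, adjusted p = 7.88e-06), as was MIXL1 (−1.41 ± 0.31), and OTX2 was higher (0.99 ± 0.2, adjusted p = 0.00144). EOMES was lower (−0.62 ± 0.18), a call that ended without H9 replicate 1 (−0.5) or replicate 2 (−0.75) and with median-of-ratios size factors (−0.45). SOX1 (−0.59, adjusted p = 0.052), PAX6 (−0.33) and TBXT (−0.27) did not pass the test. limma called 4431 regions (17.02%), 2666 higher and 1765 lower, and 2101 without H9 replicate 2. voom called 7561, of which 47.4% were higher in place of 60.17%.

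In the lists, H3K27me3 was lower than in H9 at 12 streak genes and higher at 2 of 26 measured (12 and 2 adjusted over the list alone), with NKX1-2 at −3.16, CDX1 at −2.6 and LEFTY2 at 2.92 ± 0.46. It was lower at 7 and higher at 3 of 21 forebrain genes (8 and 3 adjusted over the list alone), with ZIC2 at −2.77 and ZIC1 at −2.26 ± 0.2, and POU3F1 among those higher. It was lower at 7 of 17 midbrain, hindbrain and spinal cord genes (7 adjusted over the list alone), with GBX2 at −2.79 ± 0.25, and at 4 of 12 WNT targets, 3 of 9 amnion genes and 2 of 10 neural crest genes (5, 3 and 3 adjusted over the list alone). In mesoderm 3 of 16 were lower and 1 higher (4 and 1 adjusted over the list alone), with FOXC1 at −1.98 ± 0.22. camera adjusted p ran from 0.00118 for streak to 0.0437 in these 7 lists, and adjusted p = 0.441 for each with an estimated correlation. Every list had the camera direction lower, and list genes were not told from gene ends in general. Of 17 imprinted genes 6 were lower and 2 higher (6 and 2 adjusted over the list alone, camera 0.215), with DIRAS3 at −1.33 and ZDBF2 at 1.98 ± 0.28.

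H3K4me3 was higher in untreated lines than in H9 at ZIC1 by 2.58 ± 0.29, at CCDC169 by 1.51 ± 0.18 and at HOXB13 by 3.1 ± 0.35. It was lower at PCDHA6 (−4.81 ± 0.36) and at the region of the imprinted genes PEG3 and ZIM2 (−4.59 ± 0.34), where the untreated lines held 0.178 RPM and H9 27. TMEM132C, a locus variable between reprogrammed lines, was lower (−2.37 ± 0.34). FOXC1 (1.66), GBX2 (1.72) and UTF1 (2.1) were higher, calls that ended without H9 replicate 1 (1.33, 1.27 and 1.66). SIX3 was higher by 1.28 ± 0.33 (adjusted p = 0.0372), a call that ended without H9 replicate 1 (1.44) or replicate 2 (1.12). It also ended without untreated Burb1 replicate 1 (1.13), untreated Fiaj1 replicates 1 (1.25) or 2 (1.31), untreated Hehd1 replicates 1 (1.33) or 2 (1.23), untreated Sojd3 replicate 1 (1.2) or either Sojd3 CHR replicate (1.28). The other genes fixed in advance were not called. limma called 466 regions, 310 higher, and 146 and 142 without H9 replicates 1 and 2. voom called 813, of which 49.32% were higher in place of 66.52%. Of 15 HOX genes 3 were higher (3 adjusted over the list alone), of 17 midbrain and hindbrain genes 3 (4 adjusted over the list alone), and of 8 loci variable between reprogrammed lines 3 were lower (5 adjusted over the list alone). camera adjusted p was 0.0033, 0.0033 and 3.01e-06, and adjusted p = 0.897, 0.897 and 0.63 with an estimated correlation.

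The CHR lines were compared with H9 to find what differed after CHR. H3K27me3 was higher at TGFA (5.68 ± 0.33, at 144 against 1.47 RPM) and CCDC177 (5.08 ± 0.33), at EXOC3L4 (4.74 ± 0.41) and at the transcription factor gene SCRT2 (4.49 ± 0.32). It was lower at PIK3R1 (−2.94 ± 0.31), at the serotonin receptor gene HTR7 (−2.27 ± 0.32) and at BCL11B (−2.06 ± 0.35), a regulator of neurons and T cells. PAX6 (−0.03), EOMES (−0.39), SOX1 (−0.08), SIX3 (0.09), TBXT (−0.03), OTX2 (−0.55) and MIXL1 (−0.24) were not called. limma called 1066 regions (4.1%), 749 higher and 317 lower, of which 402 had not been called in untreated lines, and it called 298 without H9 replicate 1 and 1715 without Sojd3 CHR replicate 1. voom called 2280, and 704 were called with reads thinned to the shallowest library. Of 42 protocadherins 11 were higher (13 adjusted over the list alone), in 3 regions. 8 of the 11 share the region of PCDHB10 (2.55 ± 0.3), where CHR lines averaged 178 RPM with an SD over lines of 294, and Sojd3 CHR had 17.9 and H9 9.45. TCERG1L was higher (2.65 ± 0.31) and TMEM132C lower (−1.63 ± 0.23) among the loci variable between reprogrammed lines. BMP4 was lower (−1.15 ± 0.26), a call that ended without H9 replicate 1 (−1.25) or replicate 2 (−1.05). camera called 0 of the 18 lists, with 1 at an unadjusted p under 0.05 and a lowest adjusted p of 0.481.

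For H3K4me3, PEG3 and ZIM2 (−4.48 ± 0.34), TMEM132C (−3 ± 0.34) and SMIM3 (−2 ± 0.24) were lower in CHR lines than in H9, and CRYZ (2.21 ± 0.25) and MCTS2 (1.43 ± 0.23) were higher. HTR7 was higher by 1.57 ± 0.25, a call that ended without H9 replicate 1 (1.37), and the receptor gene KDR was lower (−1.34 ± 0.22), a call that ended without H9 replicate 2 (−1.14). SOX2 (−0.04), POU5F1 (0.04), OTX2 (−0.22), SIX3 (−0.24) and the other genes fixed in advance were not called. limma called 465 regions, 270 higher, of which 249 had not been called in untreated lines, and it called 201 and 154 without H9 replicates 1 and 2. voom called 704, of which 37.22% were higher in place of 58.06%. Of 8 loci variable between reprogrammed lines 5 were lower (6 adjusted over the list alone), and of 16 mesoderm genes 1 (3 adjusted over the list alone). limma called 0 of 17 midbrain and hindbrain genes (5 lower adjusted over the list alone, 8 at an unadjusted p under 0.05) and 0 of 15 HOX genes (0 adjusted over the list alone, 4 at an unadjusted p under 0.05). camera adjusted p was 9.91e-09, 0.000328, 0.00145 and 0.0413, and adjusted p = 0.296 for the variable loci and 0.636 for the others with an estimated correlation.

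The study's question of whether CHR brings lines to the state of H9 was addressed by the distance of each line from H9, the root mean square log2 difference over regions. For H3K27me3 it went from 1.2 to 0.68 in Burb1, from 1.27 to 0.652 in Fiaj1 and from 1.11 to 0.729 in Sojd3, and from 0.669 to 0.865 in Hehd1. The mean change was −0.331 (SD 0.364, n = 4 lines, 3 of 4 closer), with an exact permutation p of 0.25, in a design of 4 lines that cannot give a p under 0.05. For H3K4me3 the mean change was −0.007 (SD 0.124, 2 of 4 closer, exact permutation p = 0.875). With a distance computed from separate replicates, which removes the part due to replicate noise, it was −0.369 for H3K27me3 (3 of 4 closer, exact permutation p = 0.25) and −0.0893 for H3K4me3 (3 of 4 closer, exact permutation p = 0.375). Burb1 then went from 0.396 to 0.354 for H3K4me3, against 0.543 to 0.616 before. Of the 4431 H3K27me3 regions in which untreated lines differed from H9, 632 differed the same way in CHR lines, where 98.2 would be shared by independent lists. For H3K4me3 these were 210 of 466 and 5.83. Both comparisons use the same H9 libraries, which favours such overlap.

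Across regions, the H3K27me3 change after CHR correlated with the difference of H9 from untreated lines at Pearson 0.705 and 0.646 (Spearman 0.541 and 0.493) with separate untreated replicates on each side. It was 0.766 in Burb1, 0.728 in Fiaj1, 0.728 in Sojd3 and −0.0126 in Hehd1. Without separate replicates it was 0.742, against 0.319 in simulated noise on the log2 scale with no effect. That noise holds no differences between lines, so it covers only what replicate spread in the shared untreated libraries gives. A pattern particular to the untreated lines enters both sides, with or without separate replicates. With separate replicates the correlation was 0.573 without the line Fiaj1 and 0.823 without Hehd1. For H3K4me3 it was 0.336 and 0.305 (Spearman 0.293 and 0.161) with separate replicates. By line it was 0.184 in Burb1, 0.433 in Fiaj1, 0.227 in Hehd1 and 0.544 in Sojd3. Leaving out Burb1, Fiaj1, Hehd1 or Sojd3 gave 0.376, 0.214, 0.481 and 0.236. Without separate replicates it was 0.437 (covariance 0.084), against 0.317 (covariance 0.0203) in such noise. These values describe regions, which are not independent replicates.

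Sojd3 CHR cells at passages 37 and 38 were measured in 1 library per mark and passage, so no test was made, and their tables were scaled separately. H3K27me3 at DUSP8 was 2.81 RPM in untreated Sojd3, 231 after CHR, 338 at passage 37 and 212 at passage 38. At KCTD16 it was 133, 2.01, 17.9 and 42.2 RPM, at NPSR1 285, 2.15, 80 and 123 RPM, and at LMAN1 474, 11.2, 166 and 236 RPM. At ZIC1 H3K4me3 was 444, 25.5, 111 and 130 RPM. Over 3639 regions where H3K27me3 rose in the other 3 lines, the median difference from untreated Sojd3 was 0.82 after CHR, 0.68 at passage 37 and 0.53 at passage 38. Over 3000 regions where it fell, the medians were −1.67, −1.27 and −0.82, against −0.34, −0.46 and −0.28 over all tested regions. For H3K4me3 the medians were 0.39, 0.37 and 0.3 over 377 regions that rose and −0.55, −0.88 and −0.64 over 1090 that fell, against 0, −0.3 and −0.14 over all tested regions.

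**Figure D5:**
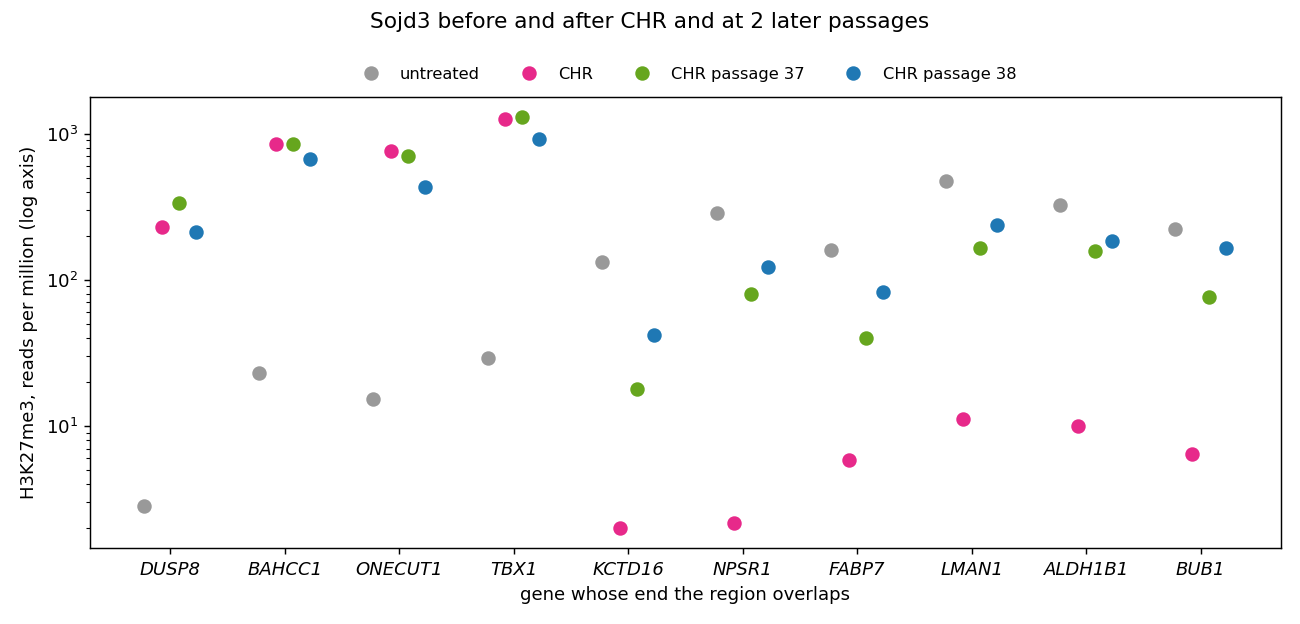
H3K27me3 in RPM on a log axis at the ends of 10 genes in Sojd3 untreated, after CHR (means of 2 replicates) and at CHR passages 37 and 38 (1 library each, scaled separately). At the falling genes the later passages lie between CHR and untreated cells, as at KCTD16 (17.9 and 42.2 RPM against 2.01 and 133).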

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

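Of the tests in this part, the 3 on Hehd1 and the 2 on the depth of CHR libraries were chosen after the results were seen.

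The CHR effect differed between lines in 9275 H3K27me3 and 560 H3K4me3 regions by limma's test of the difference itself. Among the named H3K27me3 rises that passed it, the log2 change in Hehd1 was 0.99 at DUSP8, 0.61 at KRTAP10-12, 0.58 at BAHCC1, 0.09 at EXOC3L4, 0.02 at SLC17A9, 2.33 at SLC5A5, 0.19 at ONECUT1, 0.6 at TBX1, 0.15 at ATP13A3 and 0.61 at SIX3. Among the falls it was −0.2 at KCTD16, −0.45 at NPSR1, −0.36 at FABP7, −0.11 at LMAN1, −2.19 at PHF3, −0.9 at FEZ2, −1.2 at ALDH1B1, −0.55 at GUCY2C, −1.37 at C8B, −0.52 at BUB1 and −0.13 at OTX2, and at MIXL1, which rose on average, it was −1.17. For H3K4me3 it was 3.86 at CRYZ, 0.06 at FRG2C, −0.77 at ZIC1, −0.54 at GBX2, −0.34 at FOXC1, −0.55 at PAX7, −0.41 at SCGB3A2, −0.82 at C14orf39, −0.35 at IRX1, −0.09 at RPP25 and −0.49 at SIX3.

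In Hehd1 the H3K27me3 change did not follow that of the other lines: over regions called without Hehd1, its slope on their mean change was 0.00607 (95% −0.00446 to 0.0166). The same measure for Burb1, Fiaj1 and Sojd3, each over regions called without that line and on a mean that includes Hehd1, which raises it, was 1.09, 1.36 and 1.15. With reads thinned to the total of the shallowest library, which left the share of reads in regions unmatched, the slope was −0.000835 (−0.0117 to 0.0101), which argues against the low depth of the Hehd1 CHR libraries, since fewer reads add scatter but leave a mean change in place. Exchanged labels would give a slope near −1 if Hehd1 responded like the other lines, which the value of 0.00607 argues against. If both Hehd1 conditions held a pattern near that of H9, exchanged labels would give a similarly small slope. The slope therefore cannot exclude them. The 95% intervals were taken over chromosomes and leave out the spread between libraries. Over the same regions the difference of H9 from untreated Hehd1 had a slope of −0.105 (−0.123 to −0.0867), so a candidate explanation is that untreated Hehd1 already held an H3K27me3 pattern near that of H9. Untreated Hehd1 libraries that came from other cells would give the same values, which was not tested.

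The CHR libraries were shallower than untreated ones, with medians of 5.12 against 10.96 M reads for H3K27me3 and 5.3 against 9.21 M for H3K4me3. With only libraries of at least 3 M reads, which leaves Hehd1 without CHR libraries, 88.8% of the called H3K27me3 regions and 55.47% of the H3K4me3 regions were called again in the same direction, which argues against shallow libraries as the whole cause. If untreated libraries only had less signal over background, strong regions would rise alike after CHR. Of the 1302 densest H3K27me3 regions, 58.2% (95% 54.1 to 62.3) changed by less than 0.72 in Burb1, Fiaj1 and Sojd3. Called rises had a median of 1.44 in these lines. This argues against lower signal as the only cause, but cannot tell what share of the rises it accounts for. Over all lines, 76.67% to 89.24% of H3K27me3 reads lay in the listed regions in untreated libraries and 75.02% to 83.34% in CHR libraries. Medium, matrix and IWP2 changed together in CHR cells and remain open, untested.

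Of 100 splits of the condition labels within lines, the real one included, 2 called as many H3K27me3 regions as the real one (7556, highest other 11187). For H3K4me3 it was 1 (2311, highest other 1212). Splits that mix both conditions within a line put the condition difference into the replicate spread, which lowers their counts. They therefore cannot exclude chance labels. With conditions exchanged in whole lines only, the real labels gave the most H3K4me3 calls, followed by 1309 with Hehd1 exchanged. The H3K27me3 split with 11187 calls exchanges both conditions in Hehd1 and Sojd3, the lines whose medians fell, and with median-of-ratios size factors it gives 4092 against 7936 for the real split. Exchanging the conditions in Hehd1 alone, a split not among those drawn, gives 9637 calls, and 8155 with those factors, above the real split in both cases. These splits point to a structure of the samples, namely shifts of whole lines with the scaling and a Hehd1 change that does not follow the others.

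The mitochondrial region was not among the regions compared, but its reads count in the library totals that scale all values. A larger share therefore lowers the other values of a library. The H3K4me3 share exceeded the untreated range of 0.48% to 4.06% in 7 CHR libraries: 8.39% in Burb1 replicate 1, 4.29% and 4.19% in Fiaj1 replicates 1 and 2, 5.46% and 9.49% in Hehd1 replicates 1 and 2, and 10.82% and 10.51% in Sojd3 at passages 37 and 38.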

How the results depend on the processing

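The tests with voom, thinned reads and deep libraries only (at least 3 M reads), the block for lists and leaving out lines in the correlation towards H9 were chosen after the data were seen. The counts of the 4-line comparison stayed within 1.5 times under all alternatives except those given, and the log2 changes of the genes named in the report turned sign only in the cases below. Where a value changed, the cause was not tested, except that a 2-fold minimum leaves less to call by construction. The planned count-based tests were not run, since the deposited unit is not a count. Reads were recovered, so such tests could have been run on them, as voom was. Called peaks only and overlap rules could not be applied, since all tables list the same regions.

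For H3K27me3, the 7556 calls after CHR became 4047 with a 2-fold minimum, 1752 with replicates summed and 12678 with deep libraries only, and Burb1's 7533 became 12097 with deep libraries only. The 365 in Hehd1 became 112 with median-of-ratios size factors, 220 with region totals, 30 with voom and 58 with thinned reads. The 9275 that differed between lines became 5471 with median-of-ratios, 5213 thinned and 4969 deep only. CHR lines against H9 went from 1066 to 2280 with voom and 704 thinned, and untreated lines against H9 from 4431 to 7561 with voom. For H3K4me3, the 2311 calls became 654 with a 2-fold minimum, 269 summed and 1467 without Sojd3. Fiaj1's 512 became 258 and Sojd3's 725 became 397 with deep libraries only, and Hehd1's 252 became 51 with voom and 119 thinned. The 560 that differed between lines became 366 with voom, 337 thinned and 109 deep only, and against H9 voom gave 813 for 466 in untreated and 704 for 465 in CHR lines. The correlation towards H9 of 0.705 became 0.573 without Fiaj1 and 0.823 without Hehd1, and for H3K4me3 0.336 became 0.481 without Hehd1. camera called 8, 7, 10, 3 and 4 lists where it called any, and 0 in each with an estimated correlation.

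With 1 library left out, H3K27me3 counts ran from 6543 to 8400 after CHR, 4513 to 8616 in Burb1, 3105 to 6806 in Fiaj1, 8 to 937 in Hehd1, 2910 to 7533 in Sojd3, 5234 to 12457 between lines, 2101 to 4888 for untreated lines and 298 to 1715 for CHR lines against H9. H3K4me3 counts ran from 1629 to 2676, 339 to 861, 233 to 608, 33 to 639, 282 to 932, 288 to 1003, 142 to 562 and 154 to 606 in the same order. A group left with 1 library is assumed to vary like the others. A replicate block, which replicate numbers give no reason for, gave 7484 H3K27me3 and 2200 H3K4me3 calls, and residuals of replicates sharing a number correlated at medians of 0.0297 and −0.0362 over 36 pairs of groups. Single pairs ran from −0.471 to 0.501 and from −0.433 to 0.484, with 10 pairs over 0.1 in each mark. The medians therefore do not show that such libraries were independent.

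Signs turned or reached 0 at uncalled genes. For H3K27me3 in CHR lines against H9, PAX6 (−0.03) was 0.06 with median-of-ratios, 0.03 with region totals and −0.28 to 0.22 with 1 library left out, SOX1 (−0.08) 0.02 with median-of-ratios, TBXT (−0.03) 0.06, 0.03, 0.01 thinned and −0.09 to 0.03, and SIX3 (0.09) −0.22 deep only and −0.35 to 0.53. For H3K4me3 after CHR, POU5F1 (−0.02) was 0.03, 0, 0.12 without Sojd3, 0 thinned and −0.28 to 0.24, and MIXL1 (−0.06) 0.08 without Burb1 and −0.2 to 0.07. In CHR lines against H9, SOX2 (−0.04) was 0.08, 0.02, 0.34 deep only and −0.24 to 0.17, MIXL1 (−0.05) 0.06, 0, 0.02 thinned and −0.41 to 0.31, OTX2 (−0.22) 0.14 deep only and −0.76 to 0.33, and POU5F1 (0.04) −0.09 to 0.17. In untreated lines against H9, POU5F1 (0.06) was −0.2 to 0.32, MIXL1 (0.01) −0.03 with voom and −0.34 to 0.37, OTX2 (−0.55) −1.09 to 0, and TBXT (0.11) −0.01 thinned and −0.24 to 0.45. Of called genes, MEG3 H3K4me3 (1.27) turned to −0.05 without Burb1. Median-of-ratios left 348 of the named-gene values on their side of the test, ended 21 calls and turned 6 signs. With line as the replicate, 88 of the named-gene values stayed on their side and 86 lost their call. Low depth adds scatter to single lines, but the simulated reads did not separate it from the spread of replicates.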

Other observations

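No test was added for this part, and its genes were chosen after their values were seen. The imprinted region of PEG3 and ZIM2 held H3K4me3 at 0.178 RPM in untreated lines and 0.294 RPM in CHR lines (means of 4 lines) against 27 RPM in H9. TGFA held H3K27me3 at 288 and 144 RPM against 1.47 in H9. At EXOC3L4, H3K27me3 was 66 RPM in untreated lines, with an SD of 112 over the lines, 241 in CHR lines and 9.94 in H9.

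At later passages of Sojd3, H3K4me3 lay at different places relative to CHR and untreated cells from gene to gene. At FOXC1 it was 159 RPM untreated, 18.5 after CHR, 16.7 at passage 37 and 27.8 at passage 38, whereas at GBX2 it was 269, 34.2, 104 and 135 RPM and at NANOG 290, 117, 211 and 203 RPM. At LRAT it was 139, 41.1, 30.9 and 137 RPM. The passages have 1 library each, scaled separately, so these differences were not tested.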
